A study of Mus musculus with 4 samples.

How the data were processed

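The series holds 4 bulk RNA-seq libraries of cultured mouse prostate fibroblasts, 1 for each of the conditions PBS, BuOE, PBS with radiation and BuOE with radiation. Per the labels' protocols, male C57BL/6 mice were irradiated at the pelvis under shielding at 1.2 Gy per minute, the organs were minced and digested with collagenase, and the cells were grown in medium with serum. Groups were taken from the treatment given in the labels. The values used are the deposited raw counts of reads per gene, 1 table with a column for each of the 4 libraries, and no sample column was left unused. Counts were made with featureCounts, per the submitters' processing notes, which also name Trim Galore (version 0.6.4), FastQC, Salmon (version 1.4.0) and edgeR (version 4.2.2) without their role and give the genome build as GRCm39. The treatment of strand and of reads that map to several places is not given in the sources used here, so values of near-identical genes are uncertain.

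Gene symbols and biotypes were joined by Ensembl gene ID from GENCODE M21. That annotation uses GRCm38, so names, biotypes, transcript lengths and GC content were taken from it and no coordinates. Of 56748 gene IDs, 4675 had no symbol there, and they held 1.18% of the counts in the PBS library, 1.29% in the BuOE library, 1.04% in the irradiated PBS library and 0.689% in the irradiated BuOE library. They stayed in the library totals. Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 0.987, 1.05, 0.992 and 0.972 in the same order. Genes with a mean of at least 1 CPM over the 4 libraries were kept, which left 14365, and log2 ratios were computed with a prior count of 2.

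A comparison of 2 libraries has no replicates, so none of the 4 comparisons has a test or a p-value across genes; the only tests between groups are those of the additive model. The 95% interval of each ratio is the exact binomial interval of the 2 counts given the scaled totals, and it covers counting error only, not differences between animals or cultures. Counts of genes are those at least 2-fold higher or lower. To give these counts a scale, 20 sets of libraries without any effect were drawn with the biological coefficient of variation of the additive model (0.277). Each gene was drawn independently, so these sets hold no genes that vary together. A count of 3, taken as the floor for bounds on genes with no count in a library, equals 0.102 CPM in the PBS library, 0.0990 in the BuOE library, 0.0842 in the irradiated PBS library and 0.123 in the irradiated BuOE library.

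The comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The named genes are the 10 highest and 10 lowest ratios of each comparison among genes with a mean of at least 10 CPM, leaving out gene models, pseudogenes and ribosomal or small RNA genes, then for each list described its 2 most expressed members and those with the highest and lowest ratio, a fixed set of genes of fibrosis, cell cycle, p53 and redox response, and the 5 highest and 5 lowest differences between the arms. Further genes named as examples were chosen after their values were seen, and some genes that the rule names are not reported here. Of 39 lists, 38 had at least 4 measured members. A list's shift is the median log2 ratio of its members minus the median over 10000 random lists of the same size, matched on mean expression in 20 bins, and a list is called shifted when its percentile among them is below 2.5 or above 97.5. The limits would leave out 5% of lists whose members vary independently. Members of a list are often regulated together, so any 2 cultures can place more lists outside, and a shift describes these libraries only.

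Agreement of effects was computed on library pairs that share no library. Where 2 ratios share a library, the value for simulated unchanged libraries is given beside the observed one. As a secondary analysis, radiation and BuOE were fitted as additive terms with edgeR's quasi-likelihood test, which leaves 1 residual degree of freedom, and with DESeq2 (version 1.42.0) and limma-voom (limma 3.58.1). The threshold was an adjusted p of 0.05.

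The steps were tested on simulated counts for the radiation effect, with 14365 genes of which 100 changed by a log2 ratio of 1.5 and 100 by 3, alike in both arms. With counting error only, the median recovered ratios were 1.49 and 2.98, 100% of both sets passed 2-fold, and the additive edgeR model called 17 unchanged genes. With the dispersion of the additive model, the recovered ratios were 1.46 and 3.08, 76% and 100% passed 2-fold, the additive model called 45% and 100%, and 1241 unchanged genes passed 2-fold. The counting intervals covered the true ratio for 95.2% of genes with counting error only and for 26.6% with dispersion. Of 20 simulated unchanged lists, 2 fell outside the limits.

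Alternatives changed 1 choice at a time: DESeq2 size factors, library size alone or upper-quartile factors, no filter or a mean of 10 CPM, prior counts of 0.5 and 10, libraries thinned to the smallest total, folds of 1.5 and 4, 2-fold with the counting interval past 1.5-fold, an adjusted p of 0.1, means over list members, and lists without shared genes. Added after the data were seen were the runs without mitochondrially encoded genes and the most abundant gene ID without a symbol, with protein-coding genes only, and with random lists matched also on transcript length and GC content. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.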

Results

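RNA from cultured mouse prostate fibroblasts was sequenced in bulk, with 1 library for each of 4 conditions: PBS (phosphate-buffered saline), BuOE, PBS with radiation and BuOE with radiation. Per the labels, the animals were male mice of 8 to 10 weeks, and the irradiated animals received a total of 37.5 Gy to the pelvis, in fractions of 7.5 Gy spread over 5 days. Prostates were dissociated with collagenase and the cells were cultured before RNA was isolated. The letters BuOE are part of the chemical name of the compound in the series title, a manganese porphyrin that mimics superoxide dismutase, and the title concerns its use 3 weeks after radiation against fibrosis. The labels of these libraries give neither the dose nor the timing of BuOE. They also leave open whether the animals or the cultures received it, so each BuOE ratio compares libraries by label only. The deposited counts summed to 29.7 M reads in the PBS library, 28.9 M in the BuOE library, 35.9 M in the irradiated PBS library and 25.0 M in the irradiated BuOE library. With 1 library per condition no difference has a replicate check, so each ratio compares 2 libraries and not 2 conditions. Each ratio is a log2 ratio of TMM-scaled CPM, and the range after it is its 95% interval, which covers counting error only.

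All 4 libraries held transcripts of more than 1 cell type. Fibroblast markers summed to 5970 CPM in the PBS library, 4306 in the BuOE library, 5437 in the irradiated PBS library and 4872 in the irradiated BuOE library. Epithelial markers summed to 5362, 7202, 4666 and 7441 CPM in the same order, and Krt8, a keratin of simple epithelia, alone stood at 934, 1050, 789 and 868 CPM. The 13 mitochondrially encoded mRNAs, of which 5 lay at or below 1.52 CPM in each library (mt-Co3 being the highest of them), took 0.403% of the counts in the PBS library, 0.725% in the BuOE library, 0.864% in the irradiated PBS library and 2.64% in the irradiated BuOE library. None of the 7 lymphocyte markers reached a mean of 1 CPM. The Y-linked gene Ddx3y lay between 57.7 and 82.5 CPM in the 4 libraries, and Xist, the transcript of the inactive X chromosome, was at most 0.0823 CPM.

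**Figure D1:**
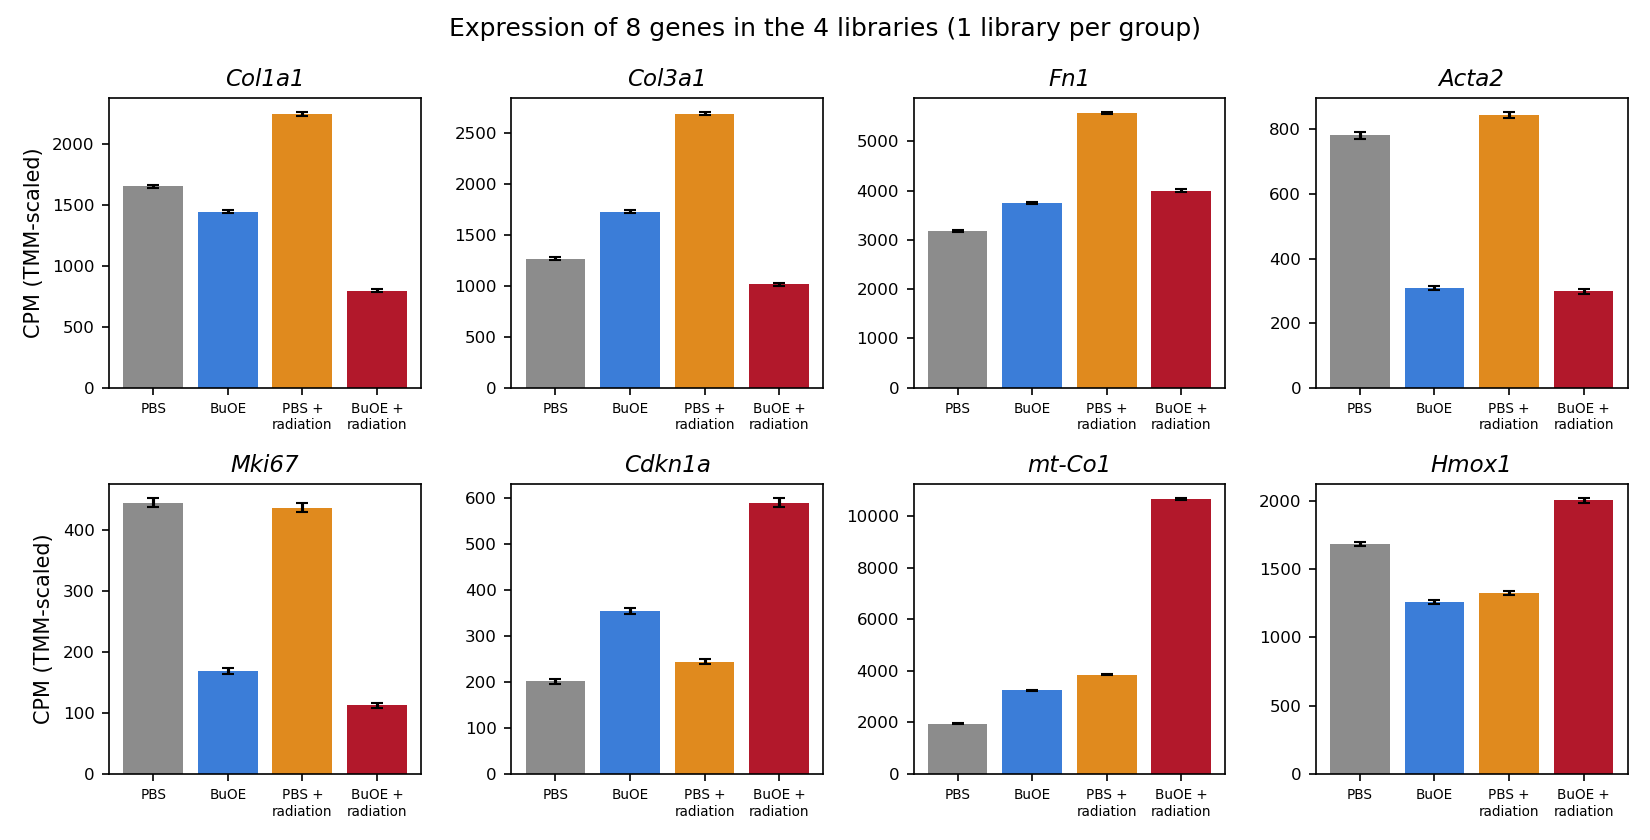
Expression of 8 genes in the 4 libraries, in TMM-scaled CPM on linear axes that start at 0; each bar is 1 library and its error bar is the 95% Poisson interval of the count. Col1a1 was highest in the irradiated PBS library (2249 CPM) and lowest in the irradiated BuOE library (795 CPM), whereas Mki67 and Acta2 were low in both BuOE libraries and mt-Co1 was highest in the irradiated BuOE library (10675 CPM).

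The first comparison asks what radiation of the animals left in cultured cells without the compound. In the PBS arm, genes of the extracellular matrix were higher in the irradiated library than in the unirradiated library. Of the 17 collagens, the main structural proteins of the matrix, 16 had a ratio above 0, and their median lay 0.39 above that of matched random lists. Col3a1 stood at 2687 against 1264 CPM (1.09, 1.07 to 1.11), Col1a1 at 2249 against 1652 CPM (0.44, 0.43 to 0.46) and Col1a2 at 1899 against 1593 CPM (0.25, 0.24 to 0.27). The highest ratio of the list was that of the basement membrane collagen Col15a1 (1.85, 1.78 to 1.91), and the lowest that of Col5a3 (-0.05, -0.09 to -0.01). Matrix glycoproteins and proteoglycans were shifted by 0.27, with 14 of 22 members above 0. Fn1, which encodes fibronectin, had a ratio of 0.81 (0.80 to 0.82), the matricellular gene Postn 0.94 (0.90 to 0.99) and Eln, which encodes elastin, 3.85 (3.50 to 4.31). Matrix-degrading proteases were shifted by 0.61, with 13 of 16 members above 0, led by Adamts4 (1.73, 1.65 to 1.81), while the stromelysin gene Mmp3 had a ratio of 0.14 (0.12 to 0.16). The protease inhibitor gene Timp1 (-0.32, -0.34 to -0.30) and the collagen cross-linking enzyme gene Lox (-0.36, -0.38 to -0.34) were lower in the irradiated library, and the list of collagen processing and cross-linking genes was not shifted (0.12), although it was called higher with means (0.22) and with lists matched on transcript length and GC content (0.18).

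Contractile genes were shifted by 0.24, with 10 of 15 members above 0. Acta2, which encodes smooth muscle actin, had a ratio of 0.11 (0.09 to 0.14), Tagln 0.17 (0.13 to 0.20) and the collagen-binding integrin gene Itga11 1.42 (1.20 to 1.68). TGF-beta response genes were shifted by 0.21, with 10 of 15 members above 0, among them Il11 (1.45, 1.41 to 1.5) and Ccn2 (0.27, 0.24 to 0.29). The ratio of Tgfb1 itself was -0.03 (-0.07 to 0.01), an interval that includes 0. Secreted factors associated with senescence were shifted by 0.60, with 19 of 21 members above 0, including Igfbp5 (1.42, 1.4 to 1.45), Cxcl5 (1.45, 1.33 to 1.57) and Il6 (0.86, 0.73 to 0.99). The list of NF-kB genes was not shifted (0.04), and that of p53 target genes (0.12) lay just inside the limit, at a percentile of 97.3, and was called higher in 7 alternatives (0.12 to 0.13). Cdkn1a, the cell cycle inhibitor induced by p53, had a ratio of 0.28 (0.23 to 0.33) and Mdm2 -0.22 (-0.28 to -0.16). Cdkn2a was near 2 CPM in both libraries, and its ratio of -0.21 had an interval that includes 0 (-0.73 to 0.30). Proliferation genes were shifted by -0.22, with 1 of 38 members above 0 and none changed 2-fold. Mki67 had a ratio of -0.03 (-0.06 to 0.01) and the replication licensing gene Mcm2 -0.52 (-0.60 to -0.45).

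NRF2 target genes, which respond to oxidants, were lower in the irradiated PBS library by a shift of -0.36, with 22 of 24 members below 0. Nqo1 had a ratio of -0.81 (-0.85 to -0.77), Hmox1 -0.35 (-0.36 to -0.33) and Gsta4 -1.19 (-1.26 to -1.13). The enzymes that remove superoxide and peroxide were not shifted as a list (-0.05), with Sod1 at -0.07 (-0.12 to -0.01), Sod2 at 0.06 (-0.01 to 0.14), Sod3 at 0.47 (0.39 to 0.54) and Cat at -0.40 (-0.47 to -0.34). All 21 cholesterol synthesis genes had ratios below 0 (shift -0.46). Glycolysis and hypoxia genes were shifted by 0.59, led by Car9 (2.59, 2.37 to 2.86), and the 8 measured mitochondrially encoded mRNAs by 1.15, with mt-Cytb at 1.36 (1.34 to 1.39). Interferon-stimulated genes were shifted by -0.16.

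Markers of several cell types differed between the same libraries. Schwann cell markers (shift 1.75), endothelial markers (1.28) and pericyte markers (1.23) were higher in the irradiated PBS library, fibroblast markers were shifted by 0.23, and adipocyte genes were lower by a shift of -1.77. Among genes with a mean of at least 10 CPM, the 10 highest ratios were those of Slc7a14 (4.94, 4.23 to 6.61), Rab3c (4.61), Prph (4.60), Tgm4 (4.38), Vat1l (4.35), Bc1 (4.02), Syt4 (4.0), Stmn2 (3.98), Eln (3.85) and Vip (3.63). Prph, Syt4, Stmn2 and Vip encode a neuronal filament, a synaptic vesicle protein, a neuronal growth-associated protein and a neuropeptide, and Tgm4 is a prostate secretory gene. The 10 lowest were Hp (-7.57, -7.99 to -7.27), Hbb-bs (-3.72), Plin4 (-3.09), Pigr (-3.08), Lrg1 (-2.38), Scd1 (-2.19), Gpd1 (-2.15), Steap4 (-2.12), Nptx1 (-2.10) and Atp2c2 (-1.92), of which Plin4, Scd1 and Gpd1 act in lipid storage and synthesis. Hp, which encodes haptoglobin, stood at 365 CPM in the unirradiated PBS library and at 1.85 CPM in the irradiated one. Reads of Hbb-bs can be shared with its near-identical paralog, so its value is uncertain.

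In all, 807 of 14365 genes were at least 2-fold higher and 146 at least 2-fold lower in the irradiated PBS library, and 16 of 38 lists were shifted higher and 7 lower. Libraries simulated without any effect, with the dispersion that a model with additive radiation and BuOE terms gave, had 1272 such genes on average, against the 953 observed. The 807 higher genes lay above the simulated maximum of 710, and the 146 lower ones below the simulated minimum of 567. With counting error only, the mean total was 2. The additive model takes the interaction as error, so the totals do not show whether radiation changed genes. Wnt response genes were shifted by 0.48, but by -0.15 among genes with a mean CPM of 10 or more. With means in place of medians the calls for Wnt response genes (0.48), fibroblast (0.23), urothelial (0.49) and macrophage markers (-0.17) and posterior Hox genes (0.32) were lost. The filter of 10 CPM ended those for interferon-stimulated genes and posterior Hox genes.

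The second comparison puts the same question to the BuOE arm. There the collagens were lower in the irradiated library, with 16 of 17 members below 0 and a shift of -0.62. Col1a1 stood at 795 against 1443 CPM (-0.86, -0.88 to -0.84), Col3a1 at 1012 against 1725 CPM (-0.77, -0.79 to -0.75) and Col1a2 at 840 against 1173 CPM (-0.48, -0.51 to -0.46); Col6a3 had the lowest ratio of the list (-1.26, -1.29 to -1.22) and Col12a1 the only one above 0 (0.52, 0.49 to 0.56). Postn was also lower (-0.69, -0.74 to -0.65), whereas matrix glycoproteins as a list (shift 0.05) and cross-linking genes (-0.08) were not shifted. Matrix-degrading proteases (shift -0.20) and TGF-beta response genes (-0.29) were lower; within the latter list Tgfbi had a ratio of -1.36 (-1.48 to -1.24), but Ccn2 0.95 (0.92 to 0.98). Tgfb1 had a ratio of -0.31 (-0.36 to -0.26) and Il6 of -0.67 (-0.80 to -0.55). Contractile genes were not shifted (0.18), although they were called higher with means (0.30), without filter (0.21) and with matching on length and GC content (0.24), and Tagln was at 0.69 (0.64 to 0.74). The ratios of Fn1 (0.09), Acta2 (-0.05), Mmp3 (0.02), Timp1 (-0.10), Lox (0.07) and Sod2 (0.05) lay near 0 and changed sign between scalings.

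p53 target genes were shifted by 0.51, with 25 of 26 members above 0, including Cdkn1a (0.74, 0.70 to 0.77), Mdm2 (0.48, 0.42 to 0.54), Plk2 (0.78, 0.74 to 0.82) and the stress cytokine gene Gdf15 (0.97, 0.81 to 1.13). Proliferation genes were shifted by -0.38, with 37 of 38 members below 0 and Mki67 at -0.59 (-0.66 to -0.52). YAP and TEAD target genes (0.50), senescence-associated secreted factors (0.39), NF-kB genes (0.40), interferon-stimulated genes (0.49), immediate early genes (0.43) and genes of ER stress (0.36) were shifted higher; Nfkbia had a ratio of 1.32 (1.26 to 1.38), Ifit3 1.12 (1.04 to 1.20) and Hspa5, an ER chaperone gene, 1.18 (1.16 to 1.20). NRF2 target genes were shifted by 0.19, with 19 of 24 members above 0, Hmox1 at 0.67 (0.65 to 0.69) and Nqo1 at 0.36 (0.31 to 0.41). Superoxide and peroxide enzymes were not shifted as a list (0.12), with Sod1 at 0.37 (0.31 to 0.43), Sod3 at -0.25 (-0.32 to -0.18) and Cat at 0.14 (0.07 to 0.21). Cdkn2a, at 0.823 against 0.495 CPM, had an interval that includes 0 (0.66, -0.30 to 1.80).

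The mitochondrially encoded mRNAs were all at least 2-fold higher in the irradiated BuOE library (8 of 8, shift 1.90), with mt-Nd2 at 2.65 (2.61 to 2.68) and mt-Co1 at 10675 against 3255 CPM (1.71, 1.70 to 1.72), while the nuclear-encoded subunits of the respiratory chain were not shifted (0.03). Cholesterol synthesis genes were lower (-0.40) and glycolysis and hypoxia genes higher (0.55), as in the PBS arm. Among markers of other cell types, adipocyte genes were higher (0.89) and Schwann cell (-0.66) and pericyte markers (-0.62) lower, and fibroblast (0.13), epithelial (-0.05) and endothelial (0.02) markers were not shifted. With the same limit of 10 CPM, the 10 highest ratios were those of Pbsn (2.79, 2.60 to 3.02), mt-Nd2, Msmb (2.55), Prl2c3 (2.55), Bc1 (2.53), mt-Cytb (2.34), Sprr1a (2.25), mt-Nd5 (2.13), Depp1 (2.11) and Rnd1 (2.11); Pbsn and Msmb are secretory genes of the prostate and Sprr1a encodes a cornified envelope protein. The 10 lowest were Nos1 (-5.58, -5.96 to -5.28), Sbp (-5.06), Vip (-5.04), Prph (-5.03), Slc7a14 (-4.66), Sv2c (-4.65), Rab3c (-4.52), Gap43 (-4.32), Spink1 (-4.25) and Syt4 (-4.11), mostly neuronal genes along with the secretory genes Sbp and Spink1.

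In this arm 326 genes were at least 2-fold higher and 709 at least 2-fold lower, and 13 lists were shifted higher and 7 lower. Simulated libraries without effect gave 1295 genes on average against the 1035 observed. The 326 higher genes lay below the simulated minimum of 585, and the 709 lower ones inside the simulated range (554 to 726). With scaling by library size alone the median ratio of all genes was -0.14 in this comparison, -0.10 between the irradiated libraries and -0.15 for the difference between the arms (0.11 with upper-quartile factors), and the list shifts are relative to such offsets. Upper-quartile scaling gave 464 higher and 595 lower, and with means in place of medians the calls for proteases, TGF-beta response genes, Schwann cell markers and prostate secretory genes were lost.

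**Figure D2:**
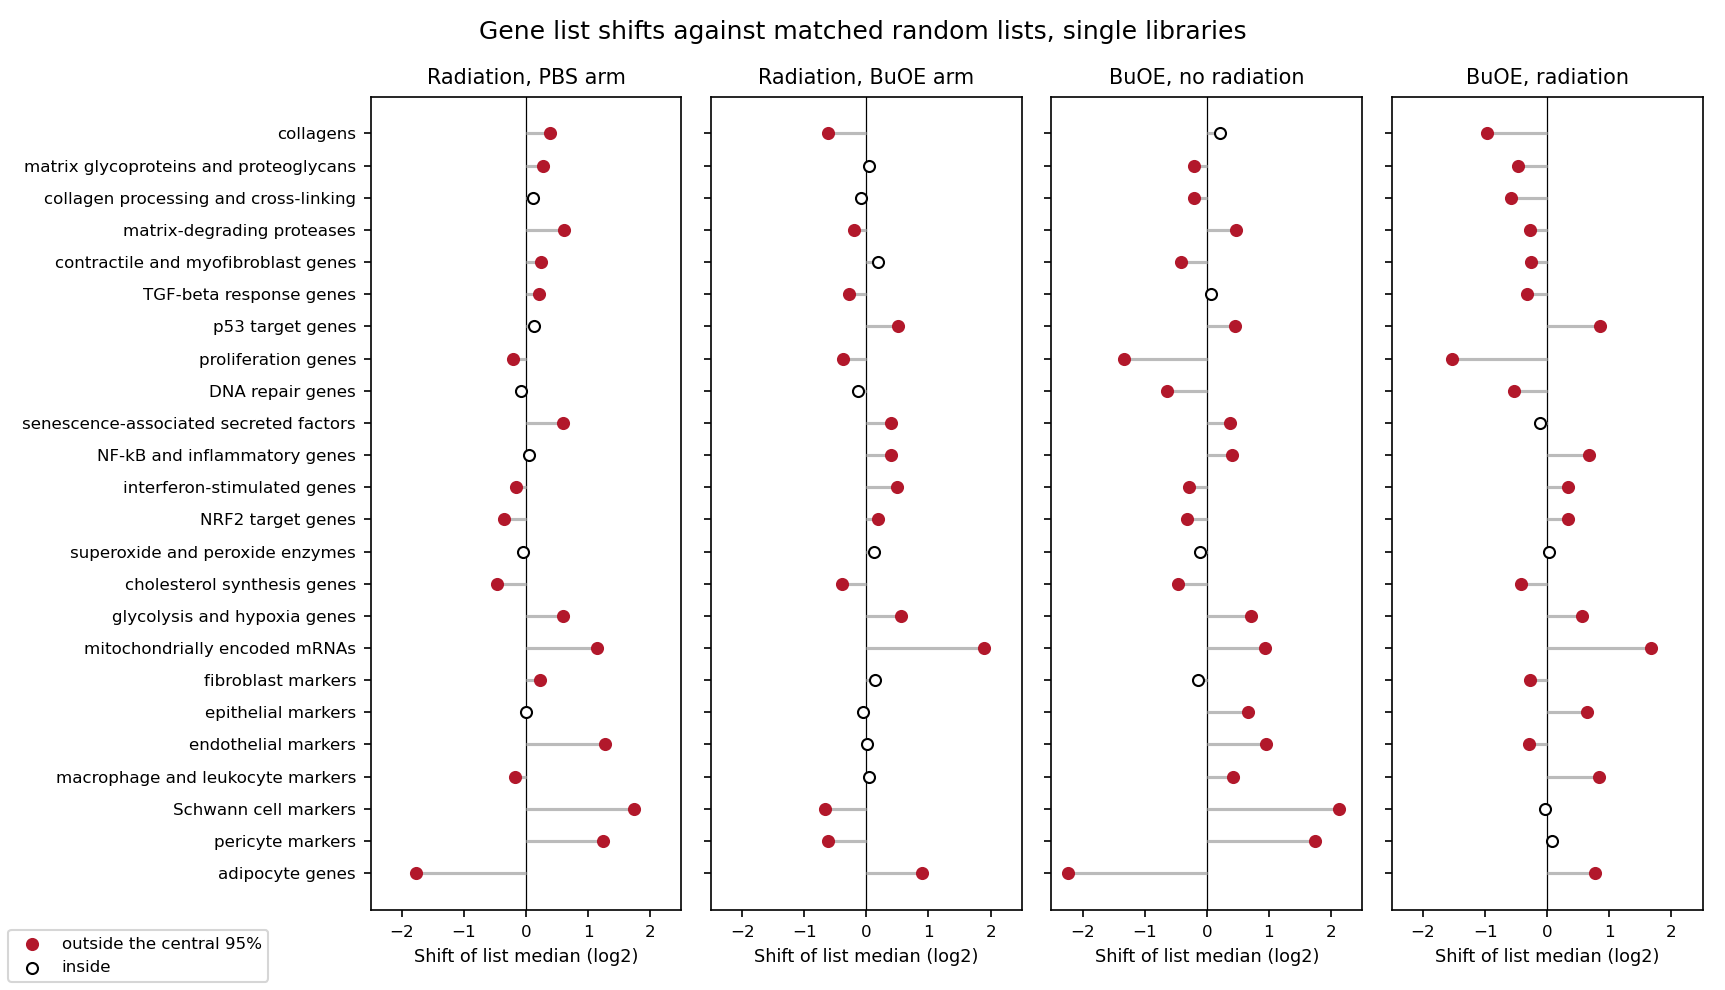
Shift of 24 gene lists in the 4 comparisons of 2 libraries, as the list's median log2 ratio minus that of 10000 random lists matched on size and mean expression; filled points lie outside the central 95% of the random lists and open points inside. The collagens lie at 0.39 for radiation in the PBS arm and at -0.62 in the BuOE arm, and proliferation genes at -1.33 and -1.53 in the BuOE comparisons.

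Set side by side, the radiation ratios of the 2 arms shared little across genes. These are ratios of separate library pairs, so that unchanged libraries give a correlation near 0 if genes vary independently. Genes of one cell type can vary together, so cultures without any effect can lie further from 0 and from the simulated values. Pearson's correlation across genes, which are not independent replicates, was -0.24 and Spearman's 0.13. Of all genes, 57.0% lay on the same side of the median ratio in both arms. At least 2-fold higher in both arms were 80 genes and lower in both 38, against 18.3 and 7.21 for independent lists and at most 34 and 35 in simulated unchanged libraries, while 300 genes were 2-fold changed in opposite directions. Genes changed 2-fold in the PBS arm, by a median of 1.49, had a median ratio of -0.30 in the BuOE arm in the PBS arm's direction, and genes changed 2-fold in the BuOE arm, by 1.43, a median of -0.17 in the PBS arm. Among genes with a mean CPM of 10 or more, these signs turned: Pearson's correlation was 0.0284 and the medians were 0.0229 and 0.0660. Glycolysis and hypoxia genes, mitochondrially encoded mRNAs and senescence-associated secreted factors were shifted higher, and cholesterol synthesis and proliferation genes lower, in both arms.

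**Figure D3:**
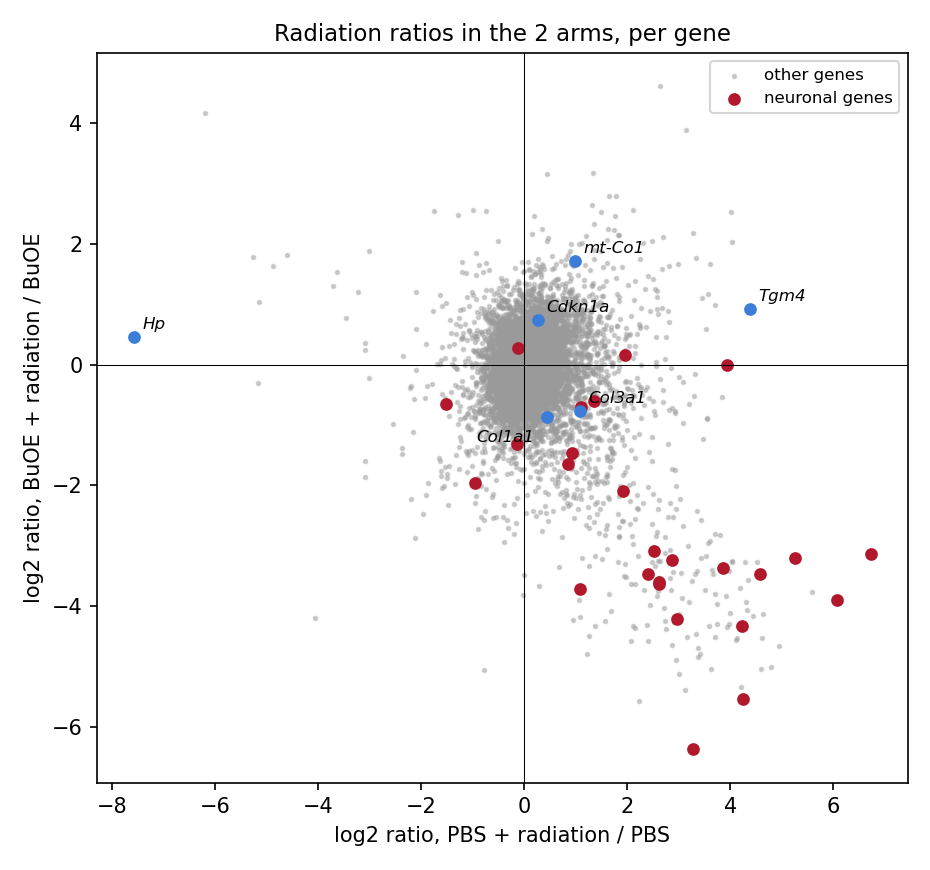
Log2 ratio of the irradiated to the unirradiated library in the PBS arm (horizontal) and in the BuOE arm (vertical); each point is 1 of 14365 genes, blue points are 6 labelled genes and red points are 26 neuronal genes of a list written after the first results were seen. The neuronal genes gather at the lower right, with medians of 2.57 in the PBS arm and -3.17 in the BuOE arm.

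The series title raises whether changes after radiation are reversed, which was compared by setting the radiation ratios of the PBS arm against the ratios of the irradiated BuOE to the irradiated PBS library. Both ratios contain the irradiated PBS library, which alone makes them run opposite: simulated unchanged libraries gave a correlation of -0.50 with dispersion and -0.42 with counting error only, whereas the observed one was -0.15. The covariance was -0.06, against -0.17 for libraries simulated unchanged with the dispersion of the additive model and -0.0077 with counting error only, so whether it lay above or below no change depends on the noise assumed. Genes 2-fold higher with radiation and then 2-fold lower with BuOE numbered 238, against 108 with dispersion and 0 with counting error only. Genes first lower and then higher numbered 32, against 200 and 0.1. The numbers of 2-fold genes that enter these counts also differed from those simulated with dispersion. On average 646 were higher with radiation and 639 lower with BuOE, against 807 and 851 observed. Lower with radiation were 626, against 146 observed. The counts therefore do not show whether radiation changes were reversed. With a mean CPM of 10 or more the correlation was 0.0808, but no unchanged libraries were simulated for that filter.

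The third comparison sets the BuOE library against the PBS library without radiation. Proliferation genes were lower in the BuOE library, all 38 with ratios below 0 and 34 of them at least 2-fold (shift -1.33). Mki67 stood at 169 against 446 CPM (-1.4, -1.44 to -1.35), Rrm2, a subunit of ribonucleotide reductase, had a ratio of -1.63 (-1.69 to -1.57) and the survivin gene Birc5 -1.76 (-1.94 to -1.59). DNA repair genes were shifted by -0.64, led by Exo1 (-1.68, -1.90 to -1.48). p53 target genes were higher by 0.46, with 21 of 26 members above 0. Cdkn1a stood at 354 against 201 CPM (0.82, 0.77 to 0.86), while Mdm2 was at -0.11 (-0.17 to -0.05). Cdkn2a was lower, at 0.495 against 2.21 CPM (-2.02, -3.08 to -1.34).

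Contractile genes were lower by a shift of -0.41 (-0.06 with means, where the call was lost), although 4 of 15 members were at least 2-fold higher and 4 at least 2-fold lower, with Acta2 at 308 against 782 CPM (-1.34, -1.38 to -1.31), Tagln at -1.15 (-1.20 to -1.10) and Actg2 at -1.48 (-1.64 to -1.34), but Myh11, a smooth muscle myosin gene, at 2.02 (1.91 to 2.14). YAP and TEAD target genes were shifted by -0.67, with Ankrd1 at -1.73 (-1.86 to -1.60) and Ccn2 at -0.80 (-0.83 to -0.78), and BMP response genes by -0.54, with the BMP antagonist gene Grem1 at -2.06 (-2.14 to -1.98). The collagens were not shifted (0.21), but were called higher with means (0.31) and after thinning (0.22): Col3a1 was at 0.45 (0.43 to 0.47), Col1a1 at -0.20 (-0.21 to -0.18) and Col1a2 at -0.44 (-0.46 to -0.42). Cross-linking genes (-0.20) and matrix glycoproteins (-0.21) were lower, with Lox at -1.06 (-1.08 to -1.04) and Fbln2 at -1.70 (-1.73 to -1.67), but Fn1 at 0.24 (0.22 to 0.25) and Postn at 1.09 (1.05 to 1.14). Matrix-degrading proteases were higher (0.47), with Adamts4 at 1.82 (1.74 to 1.90) and Mmp3 at 0.30 (0.28 to 0.32), and Timp1 was lower (-0.99, -1.01 to -0.97). TGF-beta response genes were not shifted (0.06), and the ratio of Tgfb1 (-0.08) changed sign between scalings.

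NRF2 target genes were lower in the BuOE library by a shift of -0.32, with 19 of 24 members below 0, Nqo1 at -1.13 (-1.18 to -1.09) and Hmox1 at -0.42 (-0.44 to -0.40). The superoxide and peroxide enzymes were not shifted as a list (-0.11); Sod1 was at -0.10 (-0.16 to -0.04), Sod2 at 0.29 (0.21 to 0.36), Sod3 at 0.59 (0.52 to 0.66) and Cat at -0.32 (-0.39 to -0.26). NF-kB genes (0.40), senescence-associated secreted factors (0.37) and immediate early genes (0.39) were higher, with Il6 at 1.13 (1.01 to 1.26) and the chemokine gene Ccl5 at 1.98 (1.62 to 2.41), and interferon-stimulated genes (-0.29) and ER stress genes (-0.20) were lower. Cholesterol synthesis genes were lower (-0.46), and glycolysis and hypoxia genes (0.71) and mitochondrially encoded mRNAs (0.93) higher.

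Cell type markers differed widely between these 2 libraries. Epithelial markers were higher in the BuOE library (shift 0.66, 18 of 19 members above 0), with the basal keratin gene Krt15 at 1.77 (1.69 to 1.86). Schwann cell (2.13), pericyte (1.74), endothelial (0.95) and macrophage (0.42) markers were higher too, and fibroblast markers were not shifted (-0.15). Adipocyte genes were lower (-2.23): Cfd, the adipsin gene, had a ratio of -8.21 (-15.11 to -7.32), and Adipoq had 5.76 CPM in the PBS library and no count in the BuOE library, at least 58.2-fold lower against a floor of 3 counts. From a mean of 10 CPM upward, the 10 highest ratios belonged to Slc7a14 (6.66, 5.97 to 8.33), Prph (6.59), Vip (6.21), Rab3c (5.73), Syt4 (5.71), Vat1l (5.46), Stmn2 (5.45), Nos1 (5.37), Syp (5.17) and Sv2c (4.89), with Vip at 199 against 2.62 CPM. Most of these are genes of neurons, such as the synaptic vesicle genes Syp and Sv2c. The 10 lowest belonged to Hp (-6.89, -7.24 to -6.63), Prl2c3 (-3.40), Tnfsf15 (-3.36), Ighm (-3.04), Fabp4 (-2.76), Ptx3 (-2.58), Serpinb2 (-2.54), Dlk1 (-2.5), Hbb-bs (-2.48) and Prl2c2 (-2.46). Prl2c2 and Prl2c3 are close paralogs whose reads can be exchanged, so their values are uncertain.

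In this comparison 1253 genes were at least 2-fold higher and 607 lower in the BuOE library, and 14 lists were shifted higher and 14 lower. The total of 1860 genes compares with a mean of 1289 and a maximum of 1376 in simulated libraries without effect. Only the higher genes exceeded their simulated maximum (722), while the 607 lower ones lay inside the simulated range (599 to 774). With means the calls were lost for contractile (-0.06), matrix glycoprotein (-0.09), cross-linking (-0.22), NF-kB (0.30), senescence-associated (0.24), immediate early (0.22), ER stress (-0.21) and posterior Hox genes (0.40). Without genes held by more than 1 list, that of YAP and TEAD targets was lost. The filter of 10 CPM ended the calls for nuclear long non-coding RNAs (shift -0.66), matrix glycoproteins, cross-linking genes and posterior Hox genes. Thinning ended that for matrix glycoproteins, matching on length and GC content that for ER stress genes, and no filter that for skeletal muscle markers (-1.20).

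The fourth comparison sets BuOE against PBS after radiation. The collagens were lower in the irradiated BuOE library than in the irradiated PBS library, all 17 with ratios below 0 and 8 of them at least 2-fold (shift -0.96). Col1a1 stood at 795 against 2249 CPM (-1.5, -1.52 to -1.48), Col3a1 at 1012 against 2687 CPM (-1.41, -1.43 to -1.39) and Col1a2 at 840 against 1899 CPM (-1.18, -1.20 to -1.15). Fibroblast markers were lower by a shift of -0.28, with Fap at -1.5 (-1.87 to -1.17) but Pdgfra at 0.23 (0.21 to 0.26). Matrix glycoproteins (-0.48), cross-linking genes (-0.58) and proteases (-0.28) were also lower, with Fn1 at -0.48 (-0.49 to -0.47), Postn at -0.54 (-0.59 to -0.50), Aspn at -2.69 (-3.90 to -1.97), Lox at -0.62 (-0.65 to -0.60), the procollagen processing gene Pcolce at -1.46 (-1.55 to -1.38) and Timp1 at -0.78 (-0.80 to -0.75); Mmp3 was at 0.18 (0.16 to 0.20). Contractile genes were shifted by -0.25, with Acta2 at 298 against 845 CPM (-1.5, -1.54 to -1.47) and Tagln at -0.63 (-0.67 to -0.59), but 3 of the 15 were at least 2-fold higher and 3 at least 2-fold lower. The higher ones were Myh11 (1.41, 1.33 to 1.51), Des (1.30, 1.22 to 1.38) and Cnn1 (1.04, 0.86 to 1.24). TGF-beta response genes were shifted by -0.32, with Nox4 at -1.08 (-1.45 to -0.74) and Tgfb1 at -0.36 (-0.40 to -0.31), while the ratio of Ccn2 (-0.12) changed sign between scalings. BMP response genes were lower as well (-0.44).

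Proliferation genes were lower by a shift of -1.53, all 38 below 0 and 32 of them at least 2-fold, with Mki67 at 112 against 438 CPM (-1.96, -2.02 to -1.90), and DNA repair genes by -0.53. All 26 p53 target genes had ratios above 0 (shift 0.85), led by Gdf15 (2.75, 2.53 to 3.01), with Cdkn1a at 591 against 244 CPM (1.28, 1.24 to 1.32) and Mdm2 at 0.59 (0.53 to 0.64). Cdkn2a was lower (-1.15, -2.01 to -0.48), at 0.823 against 1.91 CPM. NF-kB genes (0.67), interferon-stimulated genes (0.33) and immediate early genes (0.78) were higher, with Ccl5 at 1.94 (1.67 to 2.25) and Cxcl10 at 1.54 (1.25 to 1.87); Il6 was at -0.40 (-0.52 to -0.28), and senescence-associated secreted factors were not shifted (-0.12), but were called lower without genes held by more than 1 list (-0.35). NRF2 target genes were higher by 0.33, with 18 of 24 members above 0, Ephx1 at 1.48 (1.39 to 1.56), Hmox1 at 2005 against 1326 CPM (0.60, 0.58 to 0.62) and Nqo1 at 0.04 (-0.01 to 0.09). The superoxide and peroxide enzymes were not shifted (0.02), with Sod1 at 0.33 (0.28 to 0.39), Sod2 at 0.28 (0.20 to 0.35) and Cat at 0.22 (0.15 to 0.28), and the ratio of Sod3 (-0.13) changed sign between scalings.

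The mitochondrially encoded mRNAs were higher in the irradiated BuOE library (shift 1.68, 8 of 8 at least 2-fold), with mt-Co1 at 10675 against 3855 CPM (1.47, 1.46 to 1.48), and the nuclear-encoded respiratory chain subunits were not shifted (0.04). Cholesterol synthesis genes were lower (-0.43) and glycolysis and hypoxia genes higher (0.57). Epithelial markers (0.65, 19 of 19 members above 0), macrophage markers (0.83) and adipocyte genes (0.76) were higher and endothelial markers lower (-0.29). From a mean of 10 CPM upward, the 10 highest ratios belonged to Sprr1a (3.02, 2.98 to 3.07), Gdf15, Hbb-bs (2.53), H2-Q6 (2.47), Pbsn (2.41), Nr4a3 (2.29), Msmb (2.28), Mmp7 (2.27), Igfbp2 (2.24) and Depp1 (2.24). The 10 lowest belonged to Sbp (-5.10, -5.27 to -4.94), Spink1 (-4.38), Rab3c (-3.40), Prph (-3.05), Slc7a14 (-2.94), Gap43 (-2.68), Sv2c (-2.63), Unc5c (-2.60), Hist1h3g (-2.49) and Vip (-2.46). H2-Q6, a class I histocompatibility gene, and the histone gene Hist1h3g belong to families of near-identical genes, and their values are uncertain.

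In this comparison 548 genes were at least 2-fold higher and 851 lower, and 11 lists were shifted higher and 13 lower. The total of 1399 genes compares with a mean of 1304 and a maximum of 1372 in simulated libraries without effect. The 851 lower genes exceeded the simulated maximum of 691, while the 548 higher ones lay below the simulated minimum of 555. Upper-quartile scaling gave 765 higher and 676 lower, and single alternatives ended the calls for contractile and prostate secretory genes (means) and for TGF-beta response genes and endothelial markers (mean CPM of 10 or more).

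The BuOE ratios with and without radiation, again from separate library pairs, went together more than the radiation ratios of the 2 arms. Pearson's correlation across genes was 0.14 and Spearman's 0.41, and 66.8% of genes lay on the same side of the median ratio in both. At least 2-fold higher in both were 226 genes and lower in both 316, against 47.8 and 36.0 for independent lists and at most 38 and 40 in simulated unchanged libraries, and 231 were changed in opposite directions. Proliferation, DNA repair, contractile, cross-linking and cholesterol synthesis genes were shifted lower and p53 target, NF-kB, immediate early, glycolysis and epithelial genes higher in both comparisons. Macrophage markers (0.42 and 0.83), mitochondrially encoded mRNAs and prostate secretory genes were also higher in both. Matrix glycoproteins, BMP response genes and skeletal muscle markers were also lower in both. With means, the contractile call was lost in both (-0.06 and -0.15). The cross-linking, matrix glycoprotein, NF-kB and immediate early calls were lost with means without radiation, and the prostate secretory call with radiation. Without filter the skeletal muscle call was lost without radiation. Of the summed variances over genes of the 3 contrasts, BuOE took 44.8%, radiation 21.1% and their interaction 34.1%, where simulated unchanged libraries gave 33.4%, 33.3% and 33.4%. The simulated genes varied independently, so neither the overlaps nor the shares show whether cultures without any effect would differ as much. With a mean CPM of 10 or more Pearson's correlation was 0.43 and the share of BuOE 54.4%.

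A model with radiation and BuOE as additive terms has 1 residual degree of freedom and takes the interaction as error. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called no gene for radiation (smallest adjusted p = 0.685) or for BuOE (smallest adjusted p = 0.0891), with 1028 and 2828 of 14365 genes at an unadjusted p under 0.05. limma-voom also called none for either term, and DESeq2 called 112 genes for radiation and 836 for BuOE. The cornified envelope gene Sprr1a had the lowest adjusted p of DESeq2 for BuOE (7.78e-27), whereas edgeR's adjusted p for it was 0.0891. Its log2 change was 2.76 across the 2 BuOE and 2 PBS libraries. In each pair 1 library was irradiated, so the 2 are not replicates. That edgeR called no gene for BuOE depended on the expression filter and on the limit of adjusted p, as described under processing.

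The difference between the radiation ratios of the 2 arms, BuOE minus PBS, was not tested, since no degree of freedom is left for it. Among genes with a mean of at least 10 CPM it was highest for Hp (8.03), Hbb-bs (5.02), Prl2c3 (4.31), Plin4 (3.33) and Prl2c2 (2.75) and lowest for Prph (-9.64), Slc7a14 (-9.61), Rab3c (-9.13), Vip (-8.67) and Syt4 (-8.11). Hp was high in the PBS library only, with BuOE ratios of -6.89 without and 1.14 with radiation. A large value can thus come from 1 library. The collagens had a shift of -1.02 in the difference between the arms, with all 17 members below 0, and matrix glycoproteins one of -0.46. p53 target genes (0.41), NRF2 target genes (0.59), interferon-stimulated genes (0.70) and mitochondrially encoded mRNAs (0.81) were shifted higher, with Hmox1 at 1.02 and Nqo1 at 1.17. Superoxide and peroxide enzymes were also shifted higher (0.22), a call that was lost when lists were matched on transcript length and GC content. In total 13 lists were shifted higher and 8 lower.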

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

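Of the tests in this part, the comparisons of collagens with fibroblast markers and with epithelial dilution, of Schwann cell with adipocyte genes, and of mitochondrially encoded mRNAs with nuclear-encoded subunits and with nuclear RNAs were chosen only after the result was seen. The matching on length and GC content was added after the data were seen, and the neuronal list was written after the first results and before its own values were seen. Apart from the mitochondrially encoded mRNAs, which were higher in all 4 comparisons, the results here drew attention because the 2 libraries of one arm or radiation state differed one way and those of the other the opposite way. Each has 1 library per condition, and the difference between the differences, given as a log2 value for the BuOE arm minus the PBS arm, was not tested. Intervals over genes treat genes as independent, which they are not.

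Among gene lists, the radiation shifts went opposite ways in the 2 arms for adipocyte genes (difference 2.70), Schwann cell markers (-2.48), pericyte markers (-1.61), collagens (-1.02), matrix-degrading proteases (-0.54), TGF-beta response genes (-0.18), NRF2 target genes (0.59) and interferon-stimulated genes (0.70). The BuOE shifts without and with radiation were opposite for endothelial markers (-0.90), and also for adipocyte genes, proteases, NRF2 targets and interferon-stimulated genes, with the same differences. Radiation in the PBS arm and BuOE without radiation are both measured against the PBS library. Each of these lists had shifts of the same sign in both comparisons, which can reflect that 1 library. For BuOE without radiation, however, the collagens (0.21) and TGF-beta response genes (0.06, with a median ratio of -0.04) were not called shifted. The TGF-beta difference lay inside the central 95% of random lists, but was called lower with means (-0.39) and without genes held by more than 1 list (-0.69). Some calls behind these contrasts were lost under an alternative: with means TGF-beta response genes (-0.13), proteases (-0.14) and Schwann cell markers (-0.62) for radiation in the BuOE arm, and with a mean CPM of 10 or more interferon-stimulated genes for radiation in the PBS arm (-0.10) and endothelial markers for BuOE with radiation (-0.22). Among the named genes with a mean of at least 10 CPM, neuronal and synaptic transcripts had negative differences: Prph (-9.64), Slc7a14 (-9.61), Rab3c (-9.13), Vip (-8.67), Syt4 (-8.11), Vat1l (-7.92), Nos1 (-7.80), Sv2c (-7.52), Stmn2 (-7.40), Syp (-7.25) and Gap43 (-6.71). So had Spink1 (-5.82) and Eln (-4.38), and on the other side lay Hp (8.03), Hbb-bs (5.02), Prl2c3 (4.31), Plin4 (3.33), Prl2c2 (2.75) and Ighm (2.54).

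Collagens were lower in the irradiated BuOE library than in the irradiated PBS library. Dilution by epithelial RNA would lower the collagens alike in both BuOE comparisons, since epithelial markers were about equally high in both (shifts 0.66 and 0.65). The median collagen difference between the comparisons was -0.90 (95% interval over genes -1.67 to -0.68). The collagens drew attention through that same difference, so it cannot serve as a test of dilution. Gene length and GC content are argued against, since the shift was -0.93 against lists matched on both. A lower share of fibroblasts stays open: the fibroblast marker median lay 0.65 above the collagen median, with an interval of -0.0016 to 1.14 that includes 0. A biological effect of BuOE after radiation may also account for the pattern and was not tested, nor was RNA quality, although the same library stood apart from the irradiated PBS library in its share of mitochondrially encoded mRNAs (2.64% against 0.864%), Malat1 (0.938% against 0.453%) and ribosomal protein mRNAs (4.56% against 3.27%).

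Neuronal genes were high in the BuOE library and, less so, in the irradiated PBS library (median ratio to the PBS library 2.57 for the list used here, with 20 of 26 genes at least 2-fold higher). A list of 26 measured neuronal genes was written after neuronal genes had been seen high in the BuOE library. Its median therefore cannot tell neurons carried into that culture from neuronal genes raised in other cells. With none of the genes first seen, the list had a median ratio of 4.28 to the PBS library with 22 at least 2-fold higher, as either would give. Of its abundant members, Ret (130 against 14.4 CPM), Npy (126 against 14.8 CPM) and Tubb3 (122 against 17.2 CPM) were among these, but Uchl1 (0.67), Nefl (0.81), Nefm (-0.23) and Isl1 (-0.04), which had 17.4 to 90.5 CPM in the PBS library, were not 2-fold changed. The list's median after radiation was -1.41 (-2.09 to -0.58), against the direction that a BuOE effect alike in both radiation states would give. Neuronal genes had already been seen among the lowest ratios there, and 1 library per condition cannot separate a BuOE effect from differences between cultures. Schwann cell and adipocyte genes moved apart by 4.38 (1.97 to 7.69), which argues against a lower share of fibroblasts as the only change. That reading takes adipocyte genes as not expressed by the fibroblasts, which was not tested. Neuronal cells in the dissociated tissue are a candidate source, although 11 of the 26 genes also reached 1 CPM in the PBS library (none is in another list), and an effect of BuOE limited to the unirradiated condition was not tested.

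Mitochondrially encoded mRNAs were high in the irradiated BuOE library. A joint increase of respiratory chain transcripts from both genomes is argued against, since the nuclear-encoded median lay below the mitochondrial one (-1.67, -1.88 to -1.33). Loss of cytoplasmic RNA from damaged cells stays open. Nuclear long non-coding RNAs had a median of -0.42 (-1.16 to 1.02), with Malat1 at 1.08 and Neat1 at 0.96 but Meg3 and Rian below 0. Of the 6 members 3 lay above 0 and 3 were at least 2-fold lower, so the median cannot decide. Against the unirradiated BuOE library the same list was shifted higher (0.46), with 4 of 6 members above 0. In the difference between the arms it was shifted higher too (0.65), again with 4 of 6 above 0. No other biological explanation was tested, and either a change in the cells or RNA quality could underlie the pattern.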

How the results depend on the processing

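The alternatives restricted to protein-coding genes, without mitochondrially encoded genes and the top unnamed gene ID, and with lists matched on transcript length and GC content were chosen after the data were seen. Where no reason is given, the cause was not tested. With DESeq2 size factors, thinning to the smallest library and exclusion of mitochondrially encoded genes, all 30 summary values of each stayed within their limits, and limma-voom called 0 genes, as edgeR did. Of 116 list calls, 86 held in every alternative run for the list and 30 were lost or turned in 1 or more. Of the 74 list values not called, 18 were called in 1 or more. Some lists had too few measured members in some alternatives and were not run there. No paired analysis was possible because each condition has 1 library, and leaving out a replicate does not apply.

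Counts of 2-fold genes move with the threshold and filter by construction. They are given as higher and lower for radiation in the PBS arm (main 807 and 146), radiation in the BuOE arm (326 and 709), BuOE without radiation (1253 and 607) and BuOE with radiation (548 and 851). At 1.5-fold they were 1559 and 512, 1192 and 1632, 2296 and 1523, 1579 and 2091. At 4-fold they were 231 and 31, 36 and 241, 400 and 56, 65 and 134. With a mean CPM of 10 or more they were 245 and 43, 118 and 180, 433 and 339, 245 and 347, and without filter 2330 and 1404, 2171 and 2009, 2850 and 2373, 2343 and 2241.

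In the additive model, edgeR called no gene for radiation (1028 at an unadjusted p under 0.05) or BuOE (2828). DESeq2 called 80 higher and 32 lower for radiation and 416 and 420 for BuOE. For BuOE, an adjusted p under 0.1 gave 123 higher and 211 lower, a mean CPM of 10 or more 179 and 242, and no filter 89 and 194.

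Pearson's correlation of the radiation ratios between arms (main -0.24) was 0.0284 with a mean CPM of 10 or more, -0.11 without filter, -0.26 and -0.18 with prior counts of 0.5 and 10, and -0.27 for protein-coding genes. That of the BuOE ratios (main 0.14) was 0.43, 0.0779, 0.12, 0.21 and 0.13 in the same order, and that of the ratios sharing a library (main -0.15) was 0.0808, -0.28, -0.17, -0.10 and -0.165. Genes 2-fold higher and lower in both arms (main 80 and 38) were 30 and 11 with a mean CPM of 10 or more and 299 and 157 without filter, and for BuOE (main 226 and 316) 90 and 201, then 496 and 541. The median carried into the BuOE arm (main -0.30) was 0.0229 with a mean CPM of 10 or more, 0 without filter, -0.38 with library size only, -0.25 with upper-quartile factors and -0.28 for protein-coding genes. The median carried into the PBS arm (main -0.17) was 0.0660, 0, -0.23 and -0.0770 under the first 4 of these.

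The shares of BuOE, interaction and radiation (main 44.8%, 34.1% and 21.1%) were 54.4%, 22.2% and 23.4% with a mean CPM of 10 or more, 44.1%, 35.2% and 20.7% with a prior count of 0.5, and 46.9%, 31.2% and 21.9% with 10. Without filter BuOE took 39.4% and radiation 26.9%, and for protein-coding genes interaction took 35.0% and radiation 20.2%. With means over members, 4 lists (main 7) were lower with radiation in the BuOE arm. Wnt response genes turned with a mean CPM of 10 or more, to -0.15 for radiation in the PBS arm and 0.0486 for the difference between arms, where the difference turned to -1.25 for skeletal muscle markers without filter and to -1.05 for prostate secretory genes with means. Depth limits genes with few counts, such as Cdkn2a, whose ratio for radiation in the BuOE arm was 0.66 (-0.30 to 1.80), while thinning all libraries to the smallest total moved no summary value beyond its limit.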

Other observations

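The gene lists in this part and their percentile test were planned, the single genes were chosen after their values were seen, and no explanation was tested. Secretory genes of the prostate did not go together. In the order PBS, BuOE, irradiated PBS and irradiated BuOE library, Sbp, which encodes a spermine-binding protein, stood at 757, 428, 439 and 12.8 CPM, and the protease inhibitor gene Spink1 at 18.9, 51.3, 56.1 and 2.63 CPM. Pbsn, the probasin gene, stood at 2.69, 7.26, 9.46 and 50.7 CPM, Msmb at 2.04, 7.52, 9.09 and 44.5 CPM, Defb50 at 4.12, 11.2, 12.6 and 47.5 CPM and the transglutaminase gene Tgm4 at 1.91, 45.7, 41.1 and 86.4 CPM. As a list, secretory and luminal markers were shifted by 1.31 and 0.48 for radiation in the PBS and BuOE arms and by 1.43 and 0.95 for BuOE without and with radiation. With means, the calls were lost for radiation in the BuOE arm (0.0045) and for BuOE with radiation (0.21). The summed CPM of the list went the other way (828, 610, 606 and 304), with Sbp most of the sum in the PBS, BuOE and irradiated PBS libraries.

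Skeletal muscle markers were lower in both BuOE libraries (shifts -1.20 and -0.97), although without filter the call without radiation was lost (-0.16). They were led by Myog and Myod1, the regulators of muscle differentiation. Myog had no count in either BuOE library and was at least 11.7-fold and 27.3-fold lower than in the matching PBS libraries, against a floor of 3 counts per library, and Myod1 had ratios of -3.20 (-4.40 to -2.55) and -3.74 (-5.22 to -2.98). With Myog at these bounds the list medians stayed at -1.05 and -1.05. Nuclear long non-coding RNAs were shifted by 0.46 for radiation in the BuOE arm and by -0.66 for BuOE without radiation. Metal handling genes were shifted by -0.26 for radiation in the PBS arm, with the iron exporter gene Slc40a1 at -1.01. Posterior Hox genes were shifted by 0.32 for radiation in the PBS arm and by 0.51 for BuOE without radiation, with Hoxd12 at 0.71 and 1.23. Both calls were lost with means (0.27 and 0.40) and with a mean CPM of 10 or more (0.14 and 0.37). Mesothelial markers and sex-linked control genes were shifted in none of the 4 comparisons by medians, but with means mesothelial markers were called lower for BuOE without radiation (-1.18) and higher for radiation in the BuOE arm (0.78).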
